A study of Homo sapiens with 24 samples.

How the data were processed

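The 24 libraries were made from cultured human cells treated with cycloheximide at 100 µg/mL for 10 minutes, per the labels' protocols, which arrests elongating ribosomes in place. Per the labels' protocols, lysates were run on sucrose gradients, protected RNA fragments were purified, ribosomal RNA was removed, and small-RNA sequencing libraries were built. The labels describe 1 protocol for all libraries and do not say how INPUT RNA was fragmented or selected. Each library was deposited as a table of raw counts per Ensembl gene. The submitters' processing notes name cutadapt 3.5, STAR 2.7.9 and HTSeq 2.0.2 and the build GRCh38, without the role or settings of each. The annotation release, the strand setting, the feature counted and the handling of reads that fit several places are not given in the sources used here. Counts of genes with near-identical copies, overlapping genes and antisense genes are therefore uncertain, and footprints in untranslated regions cannot be told from those in coding sequence.

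The INPUT tables list 60623 genes and those of RPF 20426, all of which are also in the INPUT tables. All tests used the 20426 shared genes, and the share of INPUT counts in the other 40197 genes ranged widely between libraries. The 8 vector and COPS7B libraries carry 5 summary lines that name no gene, and these were left out of library sizes and tests. Reads that did not align made up 19.2% and 25.2% of reads in the vector INPUT libraries, 49.7% and 30.5% in the COPS7B INPUT libraries, 49.8% and 57.8% in the vector RPF libraries and 44.6% and 44.8% in the COPS7B RPF libraries. Reads that aligned more than once made up 22.3% and 24.7%, 16.6% and 20.2%, 27.2% and 23.6%, and 22.6% and 22.4% of the same libraries.

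Groups were taken from the sample labels, with 12 groups of 2 libraries. One edgeR quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) with a mean per group was fitted to all 24 libraries, which left 12 residual degrees of freedom, because a fit of the compared libraries alone rests on very few. Genes entered the fit if they passed edgeR's expression filter with a minimum count of 10 among the INPUT libraries and among the RPF libraries, which kept 11938. Scaling by trimmed means of M-values was done within the INPUT and within the RPF libraries. This sets the middle gene to no change, so a change of translation common to all mRNAs could not be seen. TE was tested as the interaction of assay and line, for genes with a mean INPUT count of at least 10 in both lines. The difference among the 3 cancer lines was an F test of the same interaction. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, all tests being two-sided. Levels are given as CPM, counts scaled to a common library size over the shared genes. TE folds of named genes divide footprint counts pooled over a group by the mean INPUT CPM of its libraries. Where a group had no footprint count, a floor of 3 counts took its place, and the bound was taken at the lower 95% Poisson limit of the other group's footprint counts. Other intervals are 95% Poisson intervals of the cancer line's footprint counts, and none includes the spread of INPUT. With INPUT counts pooled instead of averaged, the 12 folds were 0.683 to 1.35 times as large.

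Grouping, tests and most alternatives were fixed before the data were examined. The alternatives were trimmed means over all 24 libraries together, no such scaling, DESeq2 1.42.0 with its own size factors, limma 3.58.1 with a weight per assay, no filter on low counts, a mean of at least 50 counts in both assays and lines, only the compared libraries, at least a 2-fold change, replicate numbers as a block, all genes of the INPUT tables for mRNA, and leaving out each library in turn. A further 5 were chosen after seeing the data: close replicate pairs summed, only genes counted in every compared library, limma with a weight per library, all libraries thinned to equal depth within each assay, and crossed replicate numbers in SW620. The footprint comparison of the vector line with parental HCT15 was also added after seeing the data. A lone library left in a group was assumed to vary like the other groups.

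The procedure was tested on simulated data, drawn for the 11938 real genes from the measured means, library sizes and spread. In 12 data sets with no TE change, at most 1 gene was called in any of the 4 main TE comparisons. In a planned test 200 genes in each comparison were changed in TE by 2-fold or 4-fold, over 6 data sets. It recovered 0% of the 2-fold changes in every comparison and 2% of the 4-fold changes in HCT116, 3.83% in HCT15, 0.333% in SW620 and 1% in COPS7B, with fitted medians of 1.95, 1.98, 1.60 and 1.94 for a true log2 change of 2. Of its few calls 14.3% were false in HCT116, 28.1% in HCT15, and 0% in SW620 and COPS7B. After this low recovery had been seen, a second test with 4-fold and 32-fold changes was added. It recovered 10.7%, 15.5%, 5% and 14.8% of the 4-fold and 74.7%, 84.2%, 58.8% and 80.0% of the 32-fold changes in the same order, and 4.30%, 4.93%, 4.49% and 3.23% of its calls were false. Recovery of 4-fold changes thus differed between the mixes, and under the Benjamini-Hochberg adjustment a given unadjusted p gives a lower adjusted p when more genes in the same test have smaller ones. Genes called in the real data and counted in every compared library had a median absolute log2 TE change of 2.62 in HCT116, 2.57 in HCT15 and 2.63 in SW620. The simulation gave all groups the same spread per gene, while the measured pairs differ greatly in spread, so its false-call rates and recovery may not hold for the real libraries.

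Of the 20426 shared identifiers, 0 could be paired with a gene name, because none of the 59792 lines of the reference gene table used here carries an Ensembl identifier. Results planned on named genes were therefore not made: the level of COPS7B, the IGF2BP and COP9 signalosome genes, the tests of gene lists (pathways, complexes and markers of other cell types), scaling to mitochondrially encoded mRNAs, and results without ribosomal protein genes. The planned rule for naming genes took those with an adjusted p under 0.05, at least 10 CPM in INPUT of both lines and in RPF, and TE values that do not overlap over any pairing of libraries, ranked within each comparison and, for the 3 lines together, by the smallest change. It also required a gene name, which no identifier had. Only its part on the 3 lines together was used, limited to the first 2 identifiers in each direction out of 114 eligible higher and 62 eligible lower.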

Results

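Ribosome profiling sequences the mRNA fragments that ribosomes protect from nuclease, and sets them against the RNA of the same cells. The series holds 24 libraries from 6 cultured cell populations, with 2 libraries of ribosome-protected fragments (RPF) and 2 of input RNA (INPUT) for each. The populations were 841CON, as the sample titles name it, labelled as normal colon epithelial cells, the colorectal cancer lines HCT116, HCT15 and SW620, and HCT15 cells in a further 2 forms, carrying an expression vector (labelled PLVX, called the vector line here) or overexpressing COPS7B. COPS7B is a subunit of the COP9 signalosome, a complex that removes NEDD8 from cullin ubiquitin ligases. The design text asks how translational efficiency (TE, the footprint level of a gene relative to its RNA level) in each of the 3 cancer lines differs from 841CON, and the series title places COPS7B with the RNA-binding protein IGF2BP3 in translation in colorectal cancer. The files name genes by Ensembl identifier and do not pair these with gene names, so gene groups are described by their direction of change and not by name.

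Depth differed widely. INPUT libraries held between 1237231 and 9105954 counts in genes, and RPF libraries between 84262 and 4679279. The SW620 footprint libraries were the shallowest, with 98043 and 84262 counts and a median of 4 counts per detected gene in each. The HCT116 footprint libraries held 997844 and 1012751 counts but detected 8350 and 8448 genes, fewer than the 9171 and 9074 genes of the far shallower SW620 libraries. INPUT replicate 2 of 841CON was the deepest INPUT library, at 9105954 counts, and detected 10705 of the shared genes, the fewest of the INPUT libraries. Intervals and floors given for counts cover counting error only, because reads without molecular identifiers are not independent molecules.

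**Figure D1:**
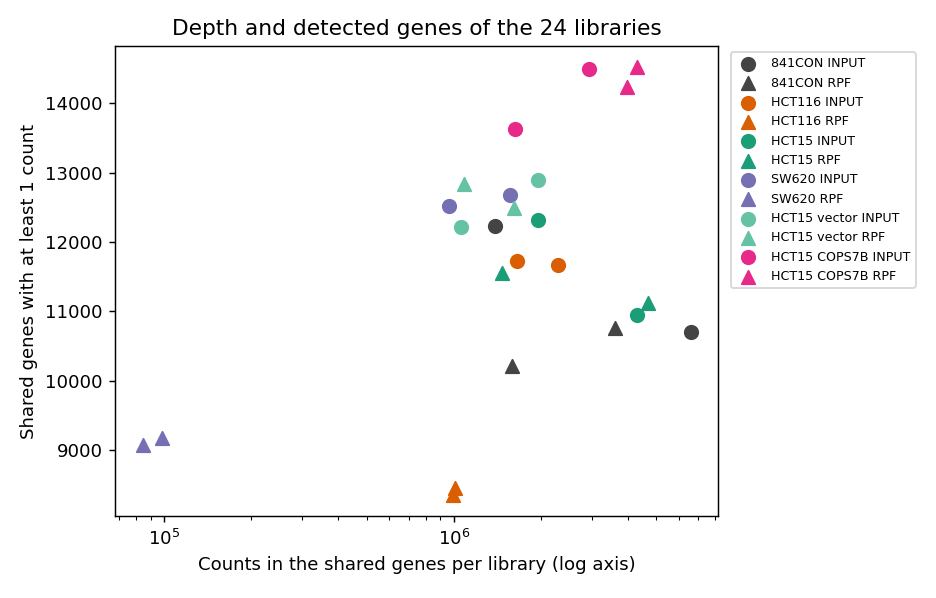
Counts per library in the genes shared by both kinds of file (horizontal, log axis) against the number of those genes with at least 1 count (vertical), one point per library, circles for INPUT and triangles for RPF. The HCT116 footprint libraries lie lowest, at 8350 and 8448 genes, although the SW620 footprint libraries at the left hold 98043 and 84262 counts.

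The replicate pairs were of 2 kinds. In 4 pairs (841CON RPF, HCT116 INPUT, HCT116 RPF and COPS7B RPF) the chi-square statistic per gene was 1.39 to 1.69 times its value under sampling noise, and the biological coefficient of variation was 0.0385 to 0.0656. In the other 8 pairs the ratio was 6.47 to 65.1 and the coefficient of variation 0.216 to 0.732. The close pairs still differed by more than sampling noise, and each library was counted as a replicate. A spread above sampling noise does not by itself show separate preparations. Counts with each close pair summed into 1 library are therefore given beside those they move by over 1.5 times. The labels do not state that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

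In HCT116, more genes had lower TE than higher TE relative to 841CON. Of 8502 genes tested, 1280 had higher and 2601 had lower TE, with a median log2 change of -0.59 over all tested genes. Among the 2601 genes with lower TE, 943 had no count in either HCT116 footprint library. Most tested genes had no called change in RNA, with or without a called change in TE. Among genes not called for TE, 3124 did not pass for RNA, while 798 had higher and 699 lower mRNA. INPUT levels did not pass the test for 783 of the genes with higher TE and 1746 of those with lower TE. A further 390 combined higher TE with lower mRNA and 384 lower TE with higher mRNA. Both were lower for 471 genes and both higher for 107. INPUT enters the 2 changes with opposite signs, so noise in it can give opposed calls. At the RNA level 2270 genes were higher and 2512 lower, and at the footprint level 2697 were higher and 4381 lower. These are counts at an adjusted p under 0.05 from edgeR's quasi-likelihood test, and 4518 genes had an unadjusted p under 0.05 for TE. With close pairs summed 1903 genes passed for TE (368 higher, 1535 lower), 2236 for mRNA (1362 higher, 874 lower) and 4391 for footprints. The larger side of the mRNA calls turned in 6 of 17 alternatives, among them 1821 higher and 1448 lower without HCT116 INPUT replicate 1, 1798 and 1375 without replicate 2, and 3266 and 2604 without 841CON INPUT replicate 1. That of the footprint calls turned among genes counted in every compared library, with 1885 higher and 1674 lower. Of the called genes, 1504 lower and 193 higher ones had no count in at least 1 compared library. Leaving such genes out therefore removes mostly lower calls by construction, and 987 higher and 1028 lower remained under that setting, with a median log2 change of -0.0043. When all libraries were thinned to equal depth 722 of 3779 tested genes passed, and where both assays averaged at least 50 counts in each line 549 of 2800 passed, with 311 higher and 238 lower.

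In HCT15 the balance was the other way, with 1032 genes higher and 451 lower in TE among 8876 tested and a median log2 change of 0.30. Of the genes with higher TE, 197 had no footprint count in either 841CON library. RNA levels were higher for 1998 genes and lower for 2229, and footprint levels higher for 3446 and lower for 2516. RNA and footprint changes correlated at r = 0.692 across 11938 genes, which are not independent replicates, and 2920 of the 3033 genes called in both moved in the same direction. For HCT116 the corresponding r was 0.474, with 2793 of 3211 genes in the same direction.

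The edgeR test for TE in HCT15 had 2733 genes at an unadjusted p under 0.05, and its count depended on fitting all 24 libraries. Fitted on the libraries of HCT15 and 841CON alone, edgeR called 0 genes for TE (1429 at an unadjusted p under 0.05) and 0 for mRNA (2712 unadjusted). That fit changes spread, scaling, filter and tested genes together, and these were not separated. Over all libraries DESeq2 called 1880 for TE and limma, with a weight per assay, 2105. The TE count was 224 with close pairs summed, 960 with genes counted in every compared library, 253 under the stricter count minimum, 413 by limma with a weight per library, and 630 or 749 without 841CON RPF replicate 1 or 2, and at equal depth 56 genes passed, of which 8 were higher and 48 lower. Without scaling by trimmed means 61.5% of the mRNA calls in HCT15 were higher, against 47.3% with it, and higher mRNA calls also outnumbered lower ones with close pairs summed (1564 against 1307), without 841CON INPUT replicate 1 (2938 against 1993), without HCT15 INPUT replicate 1 (1869 against 1328) and with trimmed means over all libraries (2225 against 2023). Footprint calls turned to more lower than higher with close pairs summed (1659 higher, 1734 lower) and at equal depth (687 higher, 862 lower).

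In SW620 the TE changes were nearly balanced, with 702 genes higher and 814 lower among 8396 tested and a median log2 change of -0.28. RNA levels were higher for 2609 genes and lower for 2690, and footprint levels were higher for 2254 and lower for 2256. Of the genes with higher TE, 160 had no footprint count in either 841CON library, and of those with lower TE 374 had higher and 95 lower mRNA. RNA and footprint changes correlated at r = 0.669, and 2617 of 2753 genes called in both moved in the same direction.

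The split in SW620 depended on scaling in edgeR's test: 46.3% of its TE calls were higher with trimmed-mean scaling and 64.6% without it, where the median log2 change was 0.06, and DESeq2 with its own size factors called 1206 higher and 564 lower. Higher calls also outnumbered lower ones at equal depth (278 against 158), with the compared libraries alone (180 against 124), by limma with a weight per library (583 against 372), with close pairs summed (181 against 162), under the stricter count minimum (32 against 24) and without SW620 INPUT replicate 2 (424 against 421). For SW620 footprints the higher share was 50.0% with and 66.9% without scaling, and DESeq2 gave 2957 higher and 1633 lower, whereas under the stricter count minimum 365 were higher and 2138 lower, with a median log2 change of -1.32. The larger side turned in 6 of 17 alternatives for SW620 mRNA and in 9 of 16 for its footprints. The TE count, 2775 at an unadjusted p under 0.05, was 343 with close pairs summed (footprints 2573), 304 with the compared libraries alone, 436 at equal depth and 955 by limma with a weight per library. It was 786 without 841CON RPF replicate 1, 845 without SW620 INPUT replicate 2 and 856 without SW620 RPF replicate 2, and 56 of 153 tested genes passed under the stricter count minimum.

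**Figure D2:**
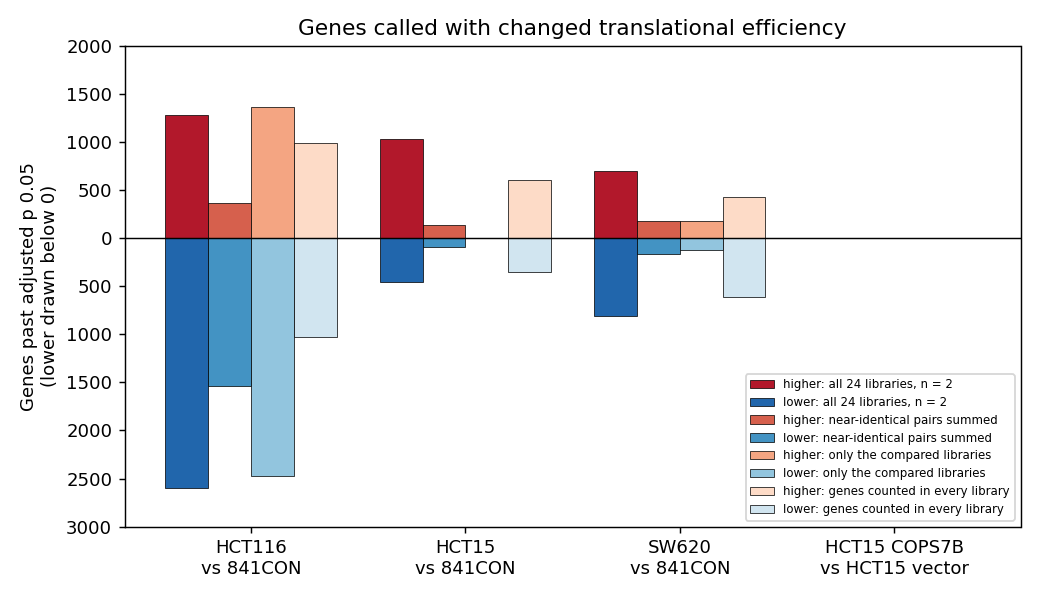
Number of genes with changed TE at an adjusted p under 0.05 (vertical; higher above 0, lower below 0) in 4 comparisons, under the fit of all 24 libraries and 3 other settings. The fit of all 24 libraries calls 1280 higher and 2601 lower in HCT116, 1032 and 451 in HCT15, 702 and 814 in SW620, and 0 for COPS7B.

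Some genes changed TE in the same direction in every cancer line. TE was higher in all 3 lines for 190 of 7707 genes tested in all of them and lower in all 3 for 74. Of the 190, 43 had no footprint count in either 841CON library, and of the 74, 11 had none in either HCT116 library. Independent lists of the same sizes would share 11.6 higher and 11.96 lower genes, and in 12 simulated data sets with no TE change, against the same 841CON libraries, 0 genes were shared in either direction. At most 1 gene was called in any single comparison of those data sets, so this 0 does not tell how many of the 190 and 74 come from the shared libraries. Part of the excess may come from the shared 841CON libraries, which are too few to split into parts of 2 per assay. The covariance of TE changes between lines was 2.74 for HCT116 and HCT15, 2.87 for HCT116 and SW620 and 3.06 for HCT15 and SW620, against simulated values of 0.323, 0.332 and 0.321. The matching correlations across genes were 0.375, 0.292 and 0.561, against 0.481, 0.236 and 0.247 with no effect. The simulation gave 841CON the spread common to all groups, while its INPUT pair varied most, at a coefficient of variation of 0.732. It also held no gaps common to both 841CON footprint libraries. The simulated values may thus be too low, and the differences do not show sharing beyond the 841CON libraries. The 190 and 74 became 39 and 9 with close pairs summed, 100 and 47 with genes counted in every compared library, 1 and 7 at equal depth, 3 and 1 under the stricter count minimum, and 0 and 0 when each comparison used its own libraries alone. The last outcome was fixed by HCT15, for which that fit called 0 genes. Without 841CON RPF replicate 1 or 2 they were 83 and 24 or 107 and 39, and without 841CON INPUT replicate 1 or 2 the lower genes were 234 or 174.

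Among the 114 genes eligible for naming out of the 190 with higher TE in all 3 lines, ENSG00000099364 and ENSG00000114904 ranked first by the smallest of their 3 fitted changes. Fitted changes are not bounds where a group had no footprint count, so this rank does not order the genes by the change that their counts support. The 841CON footprint libraries form a close pair in which 323 of 8301 mRNAs with a mean INPUT count of at least 50 had no count, and genes with 1 to 5 counts were fewer than genes with 0, at a ratio of 0.619 (95% interval 0.519 to 0.739). In the HCT116 pair 623 of 6408 had none, and bounds that rest on zeros in either pair carry this limit. Neither had a footprint count in 841CON, where their RNA stood at 93.1 ± 44.7 and 57.0 ± 16.3 CPM (SD, n = 2), so their folds are lower bounds against a floor of 3 counts over the group, taken at the lower 95% counting limit of the cancer line's footprints. For ENSG00000099364 TE at the averaged INPUT level was at least 78.3-fold higher in HCT116, at least 66.6-fold in HCT15 and at least 119-fold in SW620, where it rested on 7 footprint counts (edgeR adjusted p = 6.8e-06, 7.9e-05 and 6.1e-05). For ENSG00000114904 it was at least 129-fold higher in HCT116, at least 49.1-fold in HCT15 and at least 48.8-fold in SW620, where it rested on 21 footprint counts (edgeR adjusted p = 2.0e-06, 8.3e-05 and 3.8e-05). These bounds leave out the spread of INPUT. With INPUT counts pooled, and before the counting limit, the fold was 70.2 for ENSG00000099364 in HCT116 and 46.0 for ENSG00000114904 in HCT15. Both lie below the bounds given, even though the bounds include the counting limit and the pooled folds do not. Pooling made every fold of these 2 genes smaller, at 0.743 to 0.906 times the averaged one. With the same counting limit, each bound would therefore be lower with INPUT pooled.

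ENSG00000052802 and ENSG00000179387 ranked first in the same way among the 62 eligible of the 74 genes with lower TE in all 3 lines. For ENSG00000179387 in SW620 the fitted log2 change was -9.87, while the counts support only a bound of 3.30-fold. Bounds and folds here are again at the averaged INPUT level and leave out the spread of INPUT. ENSG00000052802 had footprints at 139 ± 27.4 CPM in 841CON, 0 in HCT116, 71.3 ± 14.3 in HCT15 and 19.4 ± 2.79 in SW620 (SD, n = 2), while its RNA was 13.7 ± 7.59, 15.4 ± 2.01, 121 ± 14.7 and 63.5 ± 7.27. Its TE was at least 102-fold lower in HCT116, 19.5-fold lower in HCT15 and 35.3-fold lower in SW620, where 4 footprint counts gave a 95% counting interval of 13.8 to 130 (edgeR adjusted p = 5.4e-06, 0.00068 and 0.00079). ENSG00000179387 had footprints at 29.2 ± 6.25 CPM in 841CON (SD, n = 2), none in HCT116 and SW620, and 1 count in HCT15. Its RNA was 12.2 ± 2.47 CPM in 841CON, 11.8 ± 3.29 in HCT116, 11.2 ± 11.4 in HCT15 and 22.7 ± 3.99 in SW620. Its TE was at least 16.6-fold lower in HCT116 and at least 3.30-fold lower in SW620 (edgeR adjusted p = 0.0014 and 0.0371), and 154-fold lower in HCT15 with a counting interval of 27.7 to 6085 (edgeR adjusted p = 0.0038). In HCT15 the SD of its RNA exceeded the mean, and with INPUT counts pooled the fold there was 105. The SW620 call of ENSG00000179387 was lost without either 841CON footprint library, without any of the SW620 libraries, and by DESeq2. None of the 4 genes passed for HCT15 when only the libraries of HCT15 and 841CON were fitted, but that fit called 0 of 8517 genes, so this says nothing particular about them.

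The 3 cancer lines differed among themselves. TE differed for 4379 of 8304 genes by edgeR's quasi-likelihood F test, a contrast of these lines in which 841CON enters through the shared spread, scaling and filter. Fitted on the libraries of the 3 cancer lines alone the count was 3944 of 7983. Calls in opposite directions relative to 841CON were made for 100 genes between HCT116 and HCT15, 92 between HCT116 and SW620 and 12 between HCT15 and SW620. ENSG00000052802 passed this test (edgeR adjusted p = 0.0044), and ENSG00000099364 did not (edgeR adjusted p = 0.17). The count was 2005 with close pairs summed, 2087 with genes counted in every compared library, 1136 at equal depth and 69 of 148 tested under the stricter count minimum.

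The vector line was compared with parental HCT15 to show what the vector and its culture add. RNA levels passed for 80 genes, 72 higher and 8 lower, and TE for 17, of which 15 were higher and 2 lower among 9738 tested. Footprint levels passed for 1250 genes, 888 higher and 362 lower. DESeq2 called 346 genes for mRNA and 210 for TE. With each culture as a block edgeR called 0 for TE (949 at an unadjusted p under 0.05). With close pairs summed edgeR called 0 for mRNA (806 at an unadjusted p under 0.05), 0 for TE (576 unadjusted) and 280 for footprints, and fitted on the compared libraries alone it called 96 for footprints. The mRNA split turned to 38 higher and 78 lower with all genes of the INPUT tables and to 25 higher and 70 lower without HCT15 INPUT replicate 1, and the 1 gene called for TE without vector INPUT replicate 1 was lower. The TE count ranged from 0 without HCT15 RPF replicate 2 to 624 without HCT15 RPF replicate 1, and the mRNA count from 3 without vector INPUT replicate 2 to 372 without HCT15 INPUT replicate 2. The footprint count was 2561 or 324 without HCT15 RPF replicate 1 or 2, and 636 or 654 without vector RPF replicate 1 or 2. By edgeR 1119 genes had an unadjusted p under 0.05 for TE.

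COPS7B overexpression went with large differences in RNA and footprints and with no called difference in TE. Relative to the vector line, RNA levels were higher for 1096 genes and lower for 992, and footprint levels were higher for 945 and lower for 1125. RNA and footprint changes correlated at r = 0.864 across 11938 genes, and 1546 of the 1547 genes called in both moved in the same direction. The level of COPS7B itself could not be looked up without gene names. Without trimmed-mean scaling 57.6% of the footprint calls were higher, against 45.7% with it, and the count of mRNA calls fell to between 1000 and 1209 and that of footprint calls to between 764 and 1370 when any 1 library was left out. With close pairs summed 1097 genes passed for mRNA and 336 for footprints, at equal depth 793 and 471, with the compared libraries alone 4190 and 4108, and by limma with a weight per library 3941 and 4023. The larger side of the mRNA calls turned in 9 of 17 alternatives, with 357 higher and 643 lower without vector INPUT replicate 1, 493 and 700 without replicate 2, 296 and 594 among genes counted in every compared library and 499 and 633 under the stricter count minimum. That of the footprint calls turned in 2 of 16.

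For TE, 0 of 9542 genes passed by edgeR's quasi-likelihood test, with 132 at an unadjusted p under 0.05. DESeq2 gave 0 with 198 unadjusted, limma 0 with 167 unadjusted under a weight per assay and 0 with 529 unadjusted under a weight per library. Fitted on the compared libraries alone, edgeR called 0 of 9522 genes, with 706 unadjusted. Without the count minimum edgeR called 13 genes, and without vector RPF replicate 2 it called 2. In data simulated for this comparison, with 200 of 11938 genes changed, 0% of 2-fold and 1% of 4-fold changes were called. In a second mix 14.8% of 4-fold and 80.0% of 32-fold changes were called. The simulation used 1 spread per gene for all groups, among them 841CON INPUT with a coefficient of variation of 0.732. The vector and COPS7B groups measured 0.0397 to 0.369, so this recovery may not hold for them. TE changes of 2-fold and 4-fold, and some of 32-fold, may have been missed, and 0 calls do not show that TE was unchanged.

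The COPS7B libraries also stood apart from the other HCT15 libraries in their correlations. COPS7B and vector INPUT libraries correlated at a mean r of 0.598 across genes, COPS7B and parental HCT15 at 0.562, and COPS7B and HCT116 at 0.659, whereas vector and parental HCT15 correlated at 0.878. Among RPF libraries COPS7B correlated best with the vector, at a mean r of 0.657, against 0.561 with parental HCT15 and 0.551 with HCT116, while vector and parental HCT15 correlated at 0.815. The comparison with the vector line therefore holds any difference between these cell populations together with that of COPS7B.

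**Figure D3:**
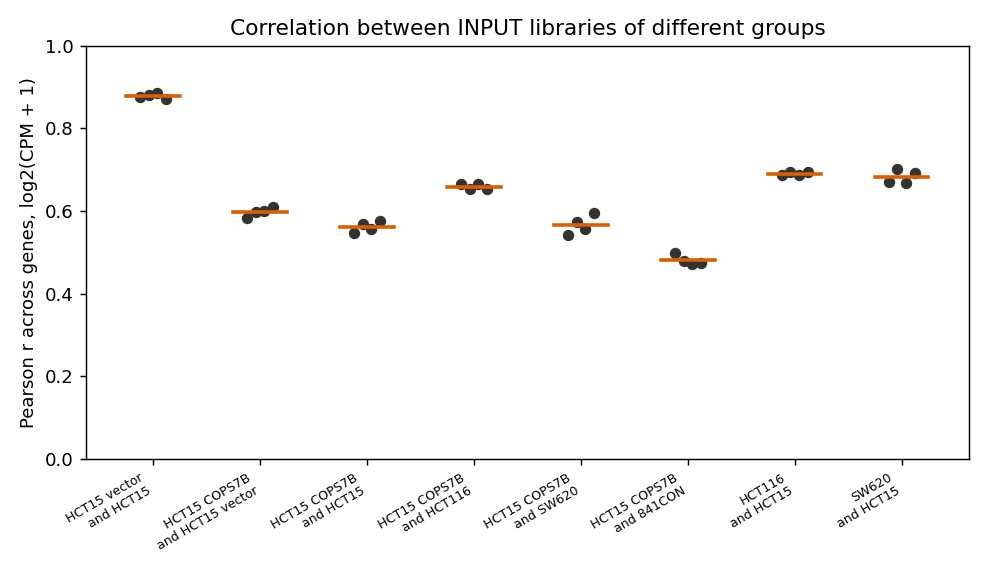
Pearson correlation across genes of log2 CPM plus 1 (vertical) between INPUT libraries of different groups, one point per pair of libraries, with the mean of each set as a bar. Vector and parental HCT15 lie at a mean of 0.878, and COPS7B libraries lie at 0.598 with the vector and 0.659 with HCT116.

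The series title joins COPS7B to translation in colorectal cancer, so its TE change was set against those of the cancer lines. Across genes, the TE change of COPS7B against the vector correlated with that of HCT116 against 841CON at r = -0.103 (Spearman -0.0981, 8047 genes), of HCT15 at -0.134 (Spearman -0.211, 8430 genes) and of SW620 at -0.0309 (Spearman -0.0732, 7997 genes). The value for HCT116 was -0.0391 with genes counted in every compared library, -0.0450 at equal depth, -0.0588 and -0.0597 by limma with a weight per assay and per library, -0.0596 without 841CON INPUT replicate 1 and -0.0642 without vector RPF replicate 1. The value for SW620 was 0.00500 by limma with a weight per assay, 0.0794 under the stricter count minimum and -0.0901 with genes counted in every compared library, and it ranged from -0.0852 without 841CON INPUT replicate 2 to 0.0362 without SW620 RPF replicate 2. The value for HCT15 was -0.331 under the stricter count minimum, -0.245 with genes counted in every compared library and -0.0754 without the count minimum, and it was -0.0405 without vector RPF replicate 1 and -0.0533 or -0.210 without 841CON INPUT replicate 1 or 2. With 0 genes called for TE in the COPS7B comparison, no overlap of calls with the cancer lines could be tested.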

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

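The tests of explanations below were chosen after the results they bear on had been seen, except the test for amplified fragments in the HCT116 footprint libraries, which was written before, and the F test among the cancer lines was planned.

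TE differed among HCT116, HCT15 and SW620 for 4379 of 8304 genes by edgeR's quasi-likelihood F test, a direct test of the difference between lines. Genes listed in the INPUT tables and absent from the RPF tables held 41.2% and 46.2% of counts in the SW620 INPUT libraries, above the 14.4% and 27.6% in 841CON. Reads that did not align made up 49.7% and 30.5% in the COPS7B INPUT libraries, above the 19.2% and 25.2% in the vector line, while in the RPF libraries COPS7B, at 44.6% and 44.8%, lay below the vector line, at 49.8% and 57.8%.

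The COPS7B INPUT libraries correlated less with the vector line (mean r = 0.598) than vector and parental HCT15 did with each other (0.878). Depth is argued against, since with all INPUT libraries thinned to one total the values were 0.592 and 0.870. A mixture in which unaltered HCT15 cells give well over 5% of the RNA is argued against too. Of all 4431 genes on in every parental and vector library, 135 lay under 5% of their vector level in COPS7B. In HCT116 60 did, and in SW620 84. A share near or under 5% stays open, since genes silent in the other cells would then lie near or under that level. Cells of another line under the HCT15 label stay open, with values on both sides. Of 4989 genes on in parental HCT15 (at least 20 CPM in each of its libraries), 42 were off in COPS7B (a mean of at most 1). This is close to the 43 for HCT116 and 52 for SW620, against 0 for the vector line. Only 1 of the 42 had no count in all 4 COPS7B libraries, against 24 in HCT116 and 23 in SW620, whose footprints are shallower. In the other direction, 273 of 7387 genes on in COPS7B were off in parental HCT15, 110 of them without a count in all 4 libraries. Of the same 7387, 192 were off in HCT116 (97 without a count), 284 in SW620 (169) and 159 in the vector line (16). COPS7B footprints correlated better with the vector (0.657) than with HCT116 (0.551) or SW620 (0.468), and at equal depth at 0.509, 0.456 and 0.404. COPS7B INPUT libraries correlated better with HCT116 (0.659) than with the vector (0.598) or SW620 (0.566). COPS7B overexpression, with changed mRNA for 2088 genes, cannot be told apart from cells of another line, because the series has a single overexpression group and the level of COPS7B could not be looked up. Silencing of the genes off in COPS7B by overexpression, or during selection of the cells, was not tested.

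In HCT116, 623 of 6408 mRNAs with a mean INPUT count of at least 50 (9.72%) had no count in either footprint library, against 0.126% to 3.89% in the other lines, and at 84262 counts per footprint library the shares were 20.1% against 2.22% to 12.4%, the highest of these in 841CON. Depth is argued against, since HCT116 RPF replicate 1 thinned to 84262 counts detected a mean of 6760.3 genes, where the SW620 libraries detected 8895.2 and 9074. Few fragments amplified many times may have left such gaps: genes with 1 to 5 counts were fewer than genes with 0, at a ratio of 0.934, but its 95% interval of 0.834 to 1.05 includes 1, and using the interval instead of the value alone was decided after the value had been seen, so this stays open, and in 841CON the ratio was lower, at 0.619 with an interval of 0.519 to 0.739 (0.798 when thinned to the HCT116 totals), and in the other 4 lines it was 1.17 to 7.68. Translation in the HCT116 line cannot be told apart from it, because the close HCT116 footprint pair, with 2 genes at 0 in one library and at 20 or more in the other, does not show that separate preparations lack the same mRNAs.

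In 4 replicate pairs the libraries differed by 1.39 to 1.69 times sampling noise, against 6.47 to 65.1 times in the other 8. A single fragment pool or library behind both members of a pair is a candidate explanation that the test left open: the 841CON and HCT116 footprint pairs had at most 2 genes at 0 in one library and at 20 or more in the other, but of the 8 pairs with large spread only 841CON INPUT (351), HCT15 INPUT (369) and HCT15 RPF (271) had many. The others had as few as 1 (COPS7B INPUT), 3 (SW620 RPF and vector INPUT), 5 (SW620 INPUT) and 12 (vector RPF), so a low number does not set the close pairs apart. Separate cultures with little spread cannot be told apart from it: the coefficient of variation of the 841CON INPUT pair was 14.9 times that of its footprint pair, but INPUT spread can arise in its own preparation. Spread between cultures would raise the chi-square ratio with count. From genes under 50 summed counts to those with at least 1000, it went from 1.68 to 1.65 in COPS7B RPF and 1.69 to 1.76 in HCT116 RPF. It rose from 1.57 to 1.99 in 841CON RPF and 1.38 to 2.29 in HCT116 INPUT. The pairs with large spread reached 57.6 to 207. The first 2 pairs thus show little sign of such spread, but cultures with too little spread to see would look alike. If a close pair is 1 preparation, the counts with close pairs summed apply. That setting leaves HCT116 with 1 library per assay, and 841CON and COPS7B with 1 footprint library each. Its counts then rest on spread borrowed from the other groups.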

How the results depend on the processing

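Summed close pairs, genes counted in every compared library, a limma weight per library, equal depth and the crossed SW620 block were chosen after seeing the data. Over 18 counts of genes, 246 of 372 alternatives stayed within 1.5 times and 126 moved further; over 3 correlations, 61 of 87 stayed. For the 4 named identifiers in 3 lines, 205 of 224 alternatives kept direction and call, 19 lost the call and 0 reversed. Alternatives in which an identifier was no longer tested are left out of this tally. Among these are the stricter minimum, and genes counted in every compared library where the identifier had a library without counts. The identifiers were also chosen for large fitted changes in the same data. Unless a sentence gives it, the cause was not tested. Values below are in the order TE, mRNA, RPF where several are given; numbers of tested genes fell under the stricter minimum, with genes counted in every library and at equal depth, which lowers counts by construction. SW620 footprints (84262 and 98043 counts) limit the stricter minimum to 153 tested genes. Results on gene names (COPS7B level, gene lists, mitochondrial scaling, ribosomal protein genes) were not run.

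Under the stricter minimum TE was 549 in HCT116, 253 in HCT15, 56 in SW620 and 0 for vector against HCT15 (442 unadjusted by edgeR); RPF was 3817 in HCT116 and 2503 in SW620; mRNA was 1132 for COPS7B and 52 for vector; the lines differed in 69, and all 3 shared 3 higher and 1 lower. The COPS7B correlations were -0.143 (HCT116), -0.331 (HCT15) and 0.0794 (SW620). With no filter TE was 13 for COPS7B and 111 for vector, mRNA 249 for vector, and r with HCT15 -0.0754.

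With close pairs summed, HCT116 had 1903, 2236 and 4391, HCT15 had TE 224 and RPF 3393, SW620 TE 343 and RPF 2573, COPS7B mRNA 1097 and RPF 336, vector TE 0 and mRNA 0 (edgeR, 576 and 806 unadjusted) and RPF 280, the lines differed in 2005, and 39 higher and 9 lower were shared. Of those TE calls 1862, 223 and 342 were also called with all libraries. With genes counted in every compared library, HCT116 had 2015, 3103 and 3559, HCT15 960, 2424 and 3762, SW620 RPF 2399, COPS7B mRNA 890, vector TE 10, the lines differed in 2087, 100 and 47 were shared, and r was -0.0391, -0.245 and -0.0901. At equal depth HCT116 had 722, 2026 and 2006, HCT15 56, 1762 and 1549, SW620 436, 2397 and 1860, COPS7B mRNA 793 and RPF 471, vector TE 0 (353 unadjusted by edgeR) and RPF 237, the lines differed in 1136, 1 and 7 were shared, and r with HCT116 was -0.0450.

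With only the compared libraries, which leaves few degrees of freedom, HCT15 had 0 for TE and 0 for mRNA (1429 and 2712 unadjusted by edgeR), HCT116 mRNA 2784, SW620 TE 304 and mRNA 2747, COPS7B mRNA 4190 and RPF 4108, vector TE 0 (643 unadjusted), mRNA 3 and RPF 96, and 0 higher and 0 lower were shared. With a limma weight per library HCT15 had TE 413 and mRNA 2007, SW620 TE 955 and mRNA 3336, COPS7B mRNA 3941 and RPF 4023, vector TE 0 (895 unadjusted), mRNA 27 and RPF 609, 106 and 16 were shared, and r with HCT116 was -0.0597. With a limma weight per assay COPS7B RPF was 3581, vector TE 93 and RPF 3237, 146 lower were shared, and r was -0.0588 with HCT116 and 0.00500 with SW620. DESeq2 gave 210 for vector TE and 346 for mRNA.

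Replicate numbers were not taken to pair INPUT with RPF libraries, since deviations of the same number did not correlate above 0.1 in every line, at -0.0303 (841CON), 0.0156 (HCT116), -0.00426 (HCT15), -0.117 (SW620), 0.223 (vector) and -0.00283 (COPS7B). With each culture as a block, TE was 954 in HCT15, 1006 in SW620 and 0 for vector (949 unadjusted by edgeR), with 126 higher shared. The other block fits stayed within 1.5 times. With SW620 numbers crossed its count was 1225, and the lines differed in 3884.

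Leaving out each library in turn gave ranges for TE of 3009 to 4186 (HCT116), 630 to 2049 (HCT15), 786 to 1848 (SW620), 0 to 2 (COPS7B) and 0 to 624 (vector); for mRNA of 3173 (without HCT116 INPUT replicate 2) to 5870, 3197 to 4931, 3758 to 5588, 1000 to 1209 and 3 to 372; for RPF of 5828 to 6135, 4152 to 5786, 2728 (without SW620 RPF replicate 1) to 3436, 764 to 1370 and 324 to 2561. The lines differed in 3438 to 4699, and 83 to 255 higher and 24 to 234 lower were shared. The correlations ranged from -0.139 to -0.0596, -0.210 to -0.0405 and -0.0852 to 0.0362.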

Other observations

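The tests in this part were written before their results were seen, and the counts of genes on or off were made after the libraries had been examined.

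Genes were taken as on in a line with at least 20 CPM in each of its 4 libraries, and as off with a mean of at most 1 over the 4. At the depth of the SW620 footprint libraries any footprint count exceeds that mean, so off in SW620 means no footprint count. Of 4610 genes on in 841CON, 189 were off in HCT116, 75 in HCT15 and 237 in SW620. In the other direction, 136 of 4595 genes on in HCT116, 133 of 4989 in HCT15 and 172 of 4998 in SW620 were off in 841CON. Between cancer lines, 65 genes on in HCT116 were off in HCT15 and 66 in SW620, 43 on in HCT15 were off in HCT116 and 52 in SW620, and 103 on in SW620 were off in HCT116 and 70 in HCT15. Vector and parental HCT15 had 0 such genes in either direction, while 273 of the 7387 genes on in COPS7B were off in parental HCT15 and 159 were off in the vector line. Of the same 7387 genes, 192 were off in HCT116 and 284 in SW620.

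Changes in TE and in RNA opposed each other across genes, at r = -0.128 in HCT116, -0.102 in HCT15, -0.137 in SW620 and -0.193 for COPS7B, as translational buffering of RNA changes would give. The hypothesis tested was that the opposition comes from the INPUT libraries, which enter both changes with opposite signs. With TE and RNA changes computed from different INPUT libraries, the mean r was 0.178 in HCT15, 0.0476 in SW620 and 0.0438 for COPS7B, above the bound of -0.1 set beforehand. Noise in the shared INPUT libraries as the source would give this. The bound lay near the starting values, so passing it says little by itself. Each split used single INPUT libraries, whose added noise also brings r nearer 0. Such noise would not by itself make r positive, as it was in HCT15 at 0.0781 to 0.277 over 4 splits. In HCT116 the mean r was 0.0160, with -0.0109 to 0.0431 over 4 splits, also above the bound. Its INPUT libraries form a close pair that may hold the same noise. Such shared noise would lower r and so cannot account for this value, and the opposition did not persist in HCT116 either.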
